A study of Mus musculus with 30 samples.

How the data were processed

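RNA was sequenced from 30 samples of mouse sciatic nerve axoplasm, with 10 nerves pooled per sample. The groups came from the sample titles: input, nucleolin IP, peptide-blocked nucleolin IP, PTBP1 IP and peptide-blocked PTBP1 IP, each from naive nerve and from nerve 7 days after crush, with 3 numbered repeats. Reads came from CASAVA 1.8.2 and edgeR was used by the authors, per the submitters' processing notes, which also name the mm10 and GRCm38 builds. The aligner, the counting tool, the use of strand and the annotation release are not given in the sources used here.

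The values analysed were whole-number counts per Ensembl transcript, as deposited by the authors in 6 tables. The tables were filtered before deposit. In 4 of them every transcript had at least 5 counts in all 3 libraries of 1 group. The 6-library table of injured PTBP1 required 5 counts in blocked libraries 2 and 3, and the table of inputs required the same of injured input 2 and 3. Input results therefore hold no transcript that was absent from either of those libraries. The deposited tables also give the authors' log2 fold changes, p-values and FDR, per the file headers; these were copied for comparison only. The authors' FPKM, normalized counts and log ratios of single samples to a group, 114 columns in all, were not used here. In 3 tables the column of blocked library 3 carries the letters PCP in place of ctrl. For the PTBP1 antibody, those columns hold the same counts, transcript by transcript, as a column named ctrl in another table. For naive nucleolin no second table exists, and the column was taken as blocked library 3 because its condition, protein and number matched that title and no other. A transcript's count need not be that of its gene: over the 6 inputs Gapdh had 1 listed transcript of 13 annotated, with 633 counts, and Actb had 1037919.

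PTBP1 comparisons used the table of 12 libraries with 15041 transcripts. The counts of the smaller PTBP1 tables, with 8932 and 10954 transcripts, were identical where transcripts were shared. Nucleolin comparisons used the 11862 transcripts found in both nucleolin tables of 14181 and 15841 transcripts. Comparisons with input used the 12399 transcripts shared by the PTBP1 and input tables and the 10893 shared by the nucleolin and input tables; the input table held 15006. Counts of these tables are raw, so they were scaled together here. Coordinates and transcript classes came from the GENCODE mouse annotation on GRCm38 (release M21 in the GENCODE numbering), which held 19991 of the 20440 transcript identifiers (97.8%). In 20 symbols a spreadsheet had turned the name into a date, and the annotation's symbol was used.

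Library totals over the listed transcripts ranged from 7536033 to 22919174 counts. Naive inputs held 13895675, 15801012 and 18391743 counts, and injured inputs 7536033, 12227391 and 13346459. PTBP1 libraries held 8409056 to 22919174, and nucleolin libraries 10435407 to 21039669. Because the tables were filtered, these totals are not the full depth. No replicate pair agreed within sampling noise: chi-square per degree of freedom was at least 57.9, and correlations of log2 CPM between replicates ran from 0.513 to 0.961.

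Differences were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test, with TMM scaling, the filterByExpr filter and Benjamini-Hochberg adjustment, two-sided, at an adjusted p of 0.05. The 12 libraries of an antibody shared 1 fit, as did those 12 with the 6 inputs (18 libraries) and the 6 inputs alone. The change of enrichment with injury was an interaction contrast in the fit of 12. CPM values were computed here from the counts with TMM-scaled library sizes. Standard errors belong to the fitted log2 fold changes. Self-tests on simulated counts drew 200 changed transcripts, 50 for each of 4 fold sizes. They were drawn only from transcripts with a mean of at least 5 CPM, so recovery of less abundant ones was not measured. The sizes were chosen after the spread of the data was known.

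Gene lists (22, written from general knowledge) were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. A listed gene was represented by its tested transcript with the highest mean CPM over the libraries of the fit. That transcript can be a minor or retained-intron form. Lists with at least 3 measured members were tested. They covered the study's candidates, axonal mRNAs, published targets of nucleolin and PTBP1, ribosomal proteins, mitochondrial transcripts, nuclear noncoding RNAs, histones, myelin, repair Schwann cells, cholesterol synthesis, macrophages, neutrophils, lymphocytes, fibroblasts, endothelium, muscle, adipocytes, red blood cells, neurons, cell cycle and cytokines.

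The genes named were set by rule for each comparison except those with input. They were up to 10 rising and 10 falling transcripts with the largest change among those past the threshold, with groups fully apart, a mean of at least 5 CPM and no predicted genes. Where fewer than 5 passed, the 10 smallest p-values were taken and said not to pass. The 5 candidates Kpnb1, Mtor, Rhoa, Ncl and Ptbp1 were always taken, with up to 4 members of each list described. Rhoa, Ncl, Mtor and Kpnb1 had 1 tested transcript each, and Ptbp1 had 2 in the PTBP1 table. Against a group with 0 counts, folds are lower bounds at a floor of 3 counts over the group; with 1 to 3 counts the ratio is given with a 95% counting interval.

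The alternatives set in advance were DESeq2 size factors in edgeR, library totals without TMM, the Wald test of DESeq2 1.42.0, no filter on low counts, a filter of 1 CPM in at least 3 libraries, a fit of only the groups compared, each library left out, the replicate number as a block (by number, or by lysate pool), an absolute log2 fold change of at least 1, and camera with an estimated correlation or library totals. Alternatives added after seeing the data were the likelihood-ratio test of edgeR, limma-voom, counts summed per gene, replicates 1 and 2 of every group, the removal of Yam1, Lars2 and Gm15564, overlaps at an unadjusted p or under the likelihood-ratio test, and camera with the replicate block. Tables were prepared in Python 3.11.15 with pandas 2.3.3 and figures drawn with matplotlib 3.10.9.

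Whether replicate numbers pair the libraries was checked by correlating deviations from group means. The labels describe the numbers only as independent repeats. The block by lysate pool took libraries of the same state and number as 1 pool, which is an inference from the labels. All 3 same-number correlations were over 0.1 in 2 of 13 pairs of groups: injured and naive nucleolin IP (0.107 to 0.532) and injured PTBP1 IP and its blocked IP (0.112 to 0.298).

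The authors' deposited folds were compared with the counts after a disagreement had been seen, by correlating each deposited comparison with 602 choices of libraries from its 2 groups. In 8 of 9 comparisons all 3 libraries of each group correlated best (0.897 to 0.999). For injured nucleolin the labelled libraries gave 0.565, and injured IP 3 over injured blocked 2 gave 0.982. The cause is not known. Sample assignments were kept as labelled, and the authors' calls for that comparison were not relied on.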

Results

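The data were RNA sequencing libraries from axoplasm, the cytoplasm pressed out of the mouse sciatic nerve. Nerves were either naive or taken 7 days after a crush, and 10 nerves were pooled for each sample. Extracts were immunoprecipitated (IP) with an antibody against nucleolin or against PTBP1. Both are RNA-binding proteins: nucleolin binds and localizes mRNAs besides its role in the nucleolus, and PTBP1 is a polypyrimidine-tract binding protein that represses splicing and also acts in the cytoplasm. The background was an IP in which the antibody had first been incubated with its blocking peptide (blocked IP). Input RNA was sequenced as well. These made 10 groups of 3 libraries, 30 in all, described by the labels as independent biological repeats. Totals over the listed transcripts ran from 7536033 to 22919174 counts per library. The shallowest was injured input 1.

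The libraries differed in how many listed transcripts they detected. In the 12 PTBP1 libraries, 23.2% ± 7.31 of transcripts were at 0 counts in naive blocked IP and 12.2% ± 8.27 in naive IP (SD, n = 3). After injury the shares were 23.8% ± 6.16 and 5.12% ± 3.04. For nucleolin, 9.50% ± 6.40 were at 0 in naive blocked IP and 1.74% ± 1.07 in naive IP, and 11.5% ± 10.1 and 0.543% ± 0.531 after injury. In every IP and blocked IP group library 3 had the fewest transcripts at 0. In naive nucleolin blocked IP, libraries 1, 2 and 3 had 14.7%, 11.45% and 2.348% at 0. The reason was not traced. The transcript Yam1 alone took 38.15%, 19.55% and 5.374% of the counts of the 3 injured inputs. Yam1, Lars2 and Gm15564 were handled here as possible sites of ribosomal RNA reads, which was not tested.

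The first comparison asked how the RNA content of the nerve extract changed 7 days after crush. Injury raised transcripts of macrophages and of dividing cells and lowered transcripts of cholesterol synthesis and fat cells, with the counts and tests of each list given below. Arg1, the arginase of alternatively activated macrophages, stood at 678 ± 90.8 CPM (counts scaled to library size) in injured input and 6.21 ± 0.784 CPM in naive input (SD, n = 3). Gpnmb, a lysosomal glycoprotein of phagocytes, stood at 1843 ± 221 against 32.1 ± 11.4 CPM. Car3, a carbonic anhydrase abundant in fat, fell from 1699 ± 299 to 59.2 ± 35.3 CPM. Of 14095 transcripts tested, 2037 rose and 1887 fell at an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment; they belonged to 3753 genes. In 44.3% of transcripts every library of one group lay above every library of the other, where chance gives 10%.

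Among the largest rises in input, F7, coagulation factor VII, had 39.1 ± 6.75 CPM in injured input and no count in naive input, which makes it at least 689-fold higher (floor of 3 counts over the group). Intervals and floors given here cover counting error only. Galnt6, a glycosyltransferase, had 3 naive counts, for a ratio of 199 with a 95% counting interval of 67.5 to 969. Rptoros, annotated antisense to Rptor, had 2 naive counts and a ratio of 401 (interval 110 to 3320); whether the counting used strand is not given in the sources used here. Cxcl5, a neutrophil-attracting chemokine, rose by 6.87 on the log2 scale, Irg1, which makes itaconate in activated macrophages, by 6.82, Il1a by 6.66, Alox15 by 6.58, Lrrc15 by 6.43 and Mcoln3 by 6.37. The largest falls among the listed transcripts were a transcript of Pmp22, which encodes a compact-myelin protein (log2 fold change -6.32), the alpha-globin Hba-a1 (-5.66), Pla2g2d (-5.18), Fxyd1 (-4.96) and Cyp2e1 (-4.94). Inputs list only transcripts with at least 5 counts in both injured input 2 and injured input 3. Transcripts lost after injury are therefore missing, while those absent from naive input are kept. The number and size of falls are cut short by this, and those of rises are not.

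Gene lists fixed before the data were examined were counted and then tested with camera at a preset correlation. Of 20 measured macrophage markers 16 rose and 0 fell (adjusted p = 1.32e-17; adjusted p = 0.0192 with an estimated correlation), with Arg1, Lgals3 (6.30), Gpnmb (5.84) and the lysosomal protease Ctss (4.19) in front on the log2 scale. Of 21 cell cycle genes 16 rose and 0 fell (adjusted p = 9.7e-19; adjusted p = 0.0192 with an estimated correlation), among them Cdk1, the mitotic kinase (5.87), Plk1 (4.60), Birc5 (4.46) and Ccna2 (4.41). Of 17 cytokines and chemokines 10 rose and 0 fell (adjusted p = 1.3e-08; adjusted p = 0.0393 with an estimated correlation), including Osm (6.28), Il1b (5.22) and Cxcl2 (4.94). Of 4 neutrophil genes 3 rose (adjusted p = 0.000998; adjusted p = 0.176 with an estimated correlation): Ltf, at least 30.9-fold higher, Retnlg (5.51) and S100a8 (3.14). Of 11 genes of repair Schwann cells, the state that denervated Schwann cells enter, 5 rose (adjusted p = 0.000209; adjusted p = 0.051 with an estimated correlation). They included the growth factor Gdnf, at least 34.7-fold higher, Cdkn2a (2.68) and Sox4 (2.65). With adjustment over each list alone, 17 macrophage, 17 cell cycle, 12 cytokine, 3 neutrophil and 6 repair Schwann cell genes rose.

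Of 16 genes of myelin and myelinating Schwann cells 13 fell and 1 rose (adjusted p = 2.65e-13; adjusted p = 0.1 with an estimated correlation). Dhh, the hedgehog ligand of Schwann cells, changed by -4.19 on the log2 scale, Ugt8a, which makes the myelin lipid galactosylceramide, by -3.71, Mal by -3.45 and S100b by -3.43. Of 17 cholesterol synthesis genes 14 fell and 0 rose (adjusted p = 1.2e-16; adjusted p = 0.0391 with an estimated correlation), among them the enzymes Fdps (-3.76), Nsdhl (-3.66) and Sc5d (-3.19) and a retained-intron transcript of Lss (-3.42). Markers of neighbouring tissues moved with them. All 7 adipocyte genes measured fell (adjusted p = 8.95e-12; adjusted p = 0.0393 with an estimated correlation), as Car3 (-4.85), Cfd (-4.82), Retn (-4.74) and Adipoq (-4.54) show. All 5 red blood cell genes fell (adjusted p = 2.8e-05; adjusted p = 0.051 with an estimated correlation), with Hbb-bs at -4.47, and so did 4 of 5 skeletal muscle genes (adjusted p = 0.000192; adjusted p = 0.177 with an estimated correlation), with Tnnc2 at -3.89 and Acta1 at -3.80. Adjusted over the list alone, 14 myelin, 16 cholesterol, 7 adipocyte, 5 red blood cell and 5 muscle genes fell. The globin genes and their near-identical copies share sequence, so single members are uncertain.

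The remaining lists did not pass in input, although members of most did. Of 23 mRNAs known from axons 3 rose and 7 fell (adjusted p = 0.247), including Tubb3 (2.03), Sncg (-3.83), Nrn1 (-2.78) and Stmn2 (-1.65). Among 11 neuronal markers 2 rose and 2 fell (adjusted p = 0.595); the injury-induced factor Atf3 was up by 1.65. Of 13 published nucleolin targets 4 rose and 1 fell (adjusted p = 0.168), with Top2a at 3.99, Gadd45a at 1.81 and Npm1 at 1.09. Of 15 published PTBP1 targets 2 rose and 1 fell (adjusted p = 0.836): a retained-intron transcript of Hif1a (2.87), Ptbp3 (1.32) and Ptbp2 (-0.91). Ribosomal protein genes split, 10 up and 19 down of 78 (adjusted p = 0.223), with Rps24 at 2.41 and Rpl27 at -2.07. Some of these genes were represented by retained-intron transcripts of low level, as Rpl30 (1.31 CPM in injured and 5.80 CPM in naive input) and Rpl24 (0.756 and 2.84 CPM) were. Fibroblast and matrix genes split 3 up and 7 down of 18 (adjusted p = 0.186), with Mfap5 at -4.07, Sparc at -2.99 and Dcn at -2.62. Endothelial and pericyte genes split 4 up and 2 down of 15 (adjusted p = 0.595), with a retained-intron transcript of Pecam1 at 1.63 and Cldn5 at -1.48. Of 11 histone genes 3 rose (adjusted p = 0.223), and of 4 lymphocyte genes Cd4 alone (2.77; list adjusted p = 0.223). Of 10 nuclear noncoding RNAs 3 rose and 3 fell (adjusted p = 0.955), with Snhg11 at -2.66; Rpph1, at 295 ± 443 against 25.1 ± 14.1 CPM (SD, n = 3), passed although its groups overlapped. Of the study's own candidates, a list that is not independent of these samples, 1 rose (Ncl) and 1 fell (Mtor) of 4 measured (adjusted p = 0.869). None of the 15 mitochondrially encoded transcripts listed was measured. With adjustment over each list alone, the up and down counts of these lists were 4 and 8 (axonal), 2 and 3 (neuronal), 4 and 1 (nucleolin targets), 2 and 1 (PTBP1 targets), 12 and 23 (ribosomal), 4 and 7 (fibroblast), 4 and 2 (endothelial), 3 and 0 (histones), 1 and 0 (lymphocytes) and 3 and 3 (nuclear RNAs).

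The input counts rested on few libraries and on the scaling. Without naive input 2 the number of calls was 2514 and without injured input 2 it was 2575. Scaling to library totals alone, which includes Yam1, called 846 higher and 1481 lower, so that 36.4% in place of 51.9% were higher, and moved the median over transcripts to -0.26 on the log2 scale. Changes above are relative to the median transcript.

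**Figure D1:**
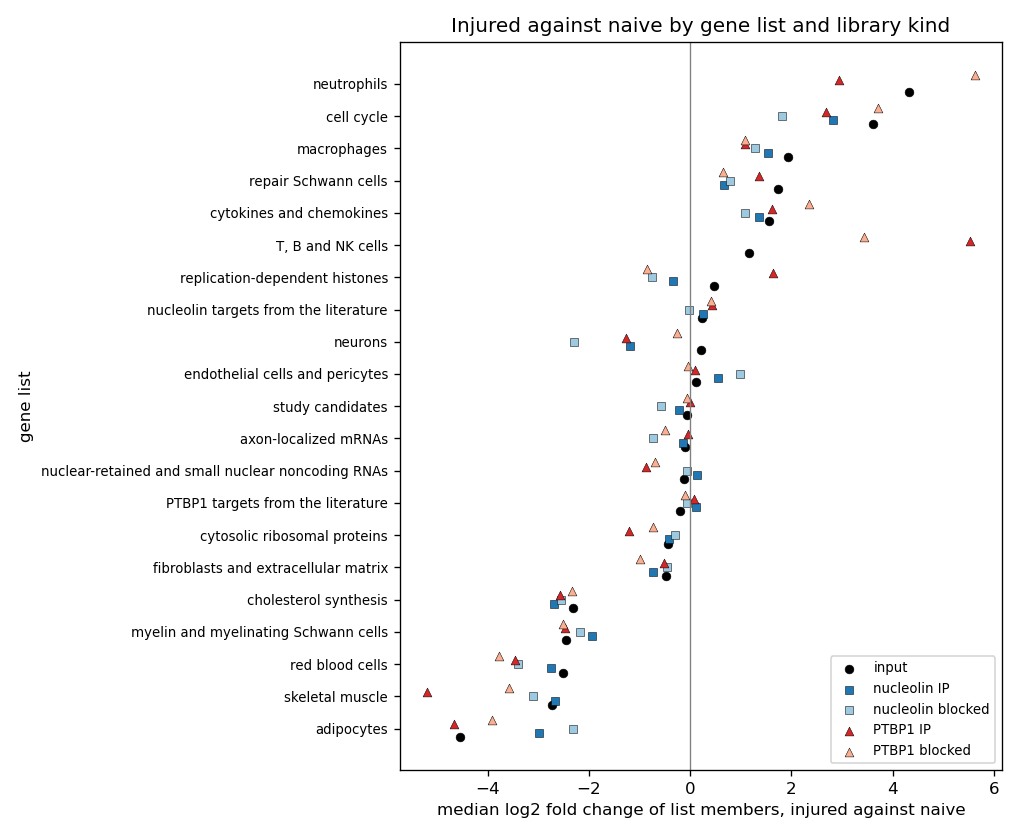
Median log2 fold change of the members of each of 21 gene lists, injured against naive, on the x axis, with 1 line per list on the y axis. Black circles show input, dark blue squares nucleolin IP, light blue squares nucleolin blocked IP, red triangles PTBP1 IP and light red triangles PTBP1 blocked IP. Macrophage and cell cycle lists lie right of 0, and myelin, cholesterol and adipocyte lists left of 0, in all 5; medians of lists with members at 0 counts in a group depend on the prior count.

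The next comparison asked which RNAs in the nucleolin IP changed with injury. It mixes RNA abundance, background and binding, so the RNAs named are not thereby bound by nucleolin. For example, Gpnmb stood at 2105 CPM in injured IP and 2699 CPM in injured blocked IP, and Mki67 at 425 and 356 CPM. Atp6v0d2 (chromosome 4, 19876841 to 19922605 on GRCm38, 8 exons), a subunit of the proton pump of osteoclasts and macrophages, was at 778 ± 155 CPM after injury and 10.5 ± 5.92 CPM in naive nerve (SD, n = 3), a log2 fold change of 6.21 (SE 0.68, adjusted p = 0.00424). Gpnmb (6.15), Cxcl2 (5.85), Tnfaip2 (5.59), the macrophage perforin Mpeg1 (4.51), the lysosomal protease Ctsd (4.34), the actin bundler Lcp1 (4.06), Arl4c (4.04), the proliferation marker Mki67 (3.93) and Cd84 (3.75) rose as well. Crispld2, a secreted matrix protein, was at 39.6 ± 12.6 against 526 ± 140 CPM (log2 fold change -3.73, SE 0.44, adjusted p = 0.00424). Inmt (-4.34), the circadian factor Hlf (-4.22), Clip3 (-4.16), Rspo1 (-3.69), P2ry1 (-3.50), the GABA transporter Slc6a13 (-3.48), Spock2 (-3.46), Car3 (-3.37) and the matrix protein Fmod (-3.34) fell.

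Among the candidates Ncl (-0.23, adjusted p = 0.941), Mtor (-0.92, adjusted p = 0.531), Rhoa (-0.54, adjusted p = 0.712), Kpnb1 (0.13, adjusted p = 0.931) and Ptbp1 (1.90, adjusted p = 0.309) did not pass. Of 11840 transcripts tested in nucleolin IP, 47 rose and 51 fell by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Groups lay fully apart in 28.8% of transcripts, against 10% by chance. Of the 98 called, 98 had the sign of the input comparison and 97 that of the blocked IP comparison, and 96 were also called in input. Over all transcripts the signs were the same in 78.4% (input) and 72.8% (blocked IP). By list, 2 of 17 cholesterol genes fell (adjusted p = 5.17e-13; adjusted p = 0.103 with an estimated correlation), Hmgcs1 by -3.06 and Hsd17b7 by -2.90. Of 13 cell cycle genes 1 rose, Mki67 (adjusted p = 1.68e-11; adjusted p = 0.00372 with an estimated correlation). Of 16 myelin genes 1 fell, the tight-junction gene Cldn19 at -2.38 (adjusted p = 3.28e-09; adjusted p = 0.177 with an estimated correlation). Of 17 macrophage genes 2 rose, Gpnmb and Cd68 at 3.07 (adjusted p = 1.26e-07; adjusted p = 0.243 with an estimated correlation), and of 13 cytokines 1 rose, Cxcl2 (adjusted p = 0.00171; adjusted p = 0.177 with an estimated correlation). Of 8 adipocyte genes 1 fell, Car3 (adjusted p = 1.12e-06; adjusted p = 0.238 with an estimated correlation). The lists of muscle, with 0 of 4 called (adjusted p = 0.00105; adjusted p = 0.243 with an estimated correlation), and red blood cells, with 0 of 5 (adjusted p = 0.0016; adjusted p = 0.259 with an estimated correlation), lay lower as sets. Adjusted over the list alone, 13 cholesterol, 10 myelin, 6 adipocyte, 2 muscle and 2 red blood cell genes fell, and 6 cell cycle and 2 macrophage genes rose.

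In this comparison the deviations of same-number libraries correlated at 0.302, 0.107 and 0.532 for numbers 1, 2 and 3. Injured IP 2 correlated better with a naive IP library of another number (0.132), so pairing is uncertain for number 2. Injured IP 3 correlated at most at -0.151 with naive IP libraries of another number, so the libraries numbered 3 shared deviations. The main fit held no term for this. With the replicate number as a block 334 transcripts were called, 154 higher and 180 lower, which included all 98. The block and an estimated correlation together left the myelin, cholesterol and cell cycle lists, each at an adjusted p of 0.0091. Leaving out 1 library lowered the 98 calls to 16 without naive IP 1, 2 without naive IP 2, 27 without naive IP 3, 10 without injured IP 1, 9 without injured IP 2 and 25 without injured IP 3.

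The same comparison in the peptide-blocked nucleolin libraries measured RNA that was carried over with the antibody blocked. Top2a, the topoisomerase of dividing cells, rose by 5.84 on the log2 scale, the kinetochore motor Cenpe by 7.36, Sgol2a, a protector of centromeric cohesion, by 6.74, Fgr by 6.43, Tnfaip2 by 5.76, Kcnn4 by 5.61 and Cxcl2 by 5.55. Rab9b (-7.26), Sowaha (-6.87), a retained-intron transcript of the glutamate receptor gene Gria3 (-6.74), Cldn22 (-6.01), Inmt (-5.27), Sc5d (-5.10), Ugt8a (-4.70) and the fatty acid synthase Fasn (-4.38) fell. Altogether 87 transcripts rose and 97 fell (184 genes) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment; groups lay apart in 24.2%, against 10% by chance. Of 16 myelin genes 3 fell, Ugt8a, S100b (-3.15) and Drp2 (-2.34) (adjusted p = 2.66e-10; adjusted p = 0.225 with an estimated correlation). Of 17 cholesterol genes 4 fell (adjusted p = 1.43e-08; adjusted p = 0.226 with an estimated correlation), and of 13 cell cycle genes 2 rose (adjusted p = 2.82e-07; adjusted p = 0.054 with an estimated correlation). Adjusted over the list alone, 11 myelin and 12 cholesterol genes fell and 6 cell cycle genes rose. Of 17 macrophage genes 1 rose (adjusted p = 0.000828; adjusted p = 0.464 with an estimated correlation). Adipocyte (adjusted p = 0.000556), red blood cell (adjusted p = 0.000922) and muscle (adjusted p = 0.00161) sets lay lower and cytokines higher (adjusted p = 0.0496), each at an adjusted p of 0.344 with an estimated correlation. With only the 6 blocked libraries in the fit 0 transcripts were called. Scaling to library totals made 61.4% in place of 47.3% of the calls higher. Leaving out 1 library gave 79 calls without naive blocked 1, 48 without naive blocked 2, 419 without naive blocked 3, 66 without injured blocked 1, 13 without injured blocked 2 and 278 without injured blocked 3.

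For PTBP1, the corresponding comparison called 1 transcript. Cxcl5 (chromosome 5, 90759378 to 90761624) was at 103 ± 69.3 CPM in injured PTBP1 IP and had no count in naive PTBP1 IP (SD, n = 3), at least 2180-fold higher (adjusted p = 0.0205). Rhoa (0.41, adjusted p = 0.842) and Mtor (-2.24, adjusted p = 0.558) did not pass. Nor did the next transcripts by p: the matrix protein Mfap5 (log2 fold change -4.13, adjusted p = 0.0548), the growth cone protein Basp1 (5.11, adjusted p = 0.0548), Lrrc15 (adjusted p = 0.0548), the Fc receptor chain Fcer1g (3.88, adjusted p = 0.12) and Ugt8a (-4.38, adjusted p = 0.124). In the blocked PTBP1 libraries Cxcl5 rose, from 1 naive count (ratio 8030, counting interval 1440 to 317000), as did Lrrc15, from 1 naive count (4830, 867 to 191000), and Arl4c (log2 fold change 9.22), while Fasn fell (-7.21). All were tested by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 14540 transcripts; groups lay apart in 29.2% of transcripts in the IP and 20.3% in the blocked IP, against 10% by chance. DESeq2 called 676 and 2497 transcripts in the IP and the blocked IP, the likelihood-ratio test of edgeR 318 and 1821, and limma-voom 214 and 637. The authors' deposited table lists 437 higher and 289 lower in the IP at an FDR under 0.05, and 631 and 765 in the blocked IP.

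As sets, 12 lists passed the threshold in the PTBP1 IP and 12 in the blocked IP, and none did so with an estimated correlation. In the IP cholesterol genes lay lower (adjusted p = 6.13e-10; adjusted p = 0.0671 with an estimated correlation), as did myelin genes (adjusted p = 1.7e-08; adjusted p = 0.0887 with an estimated correlation) and adipocyte genes (adjusted p = 1.11e-07; adjusted p = 0.195 with an estimated correlation). Cell cycle genes lay higher (adjusted p = 4.14e-07; adjusted p = 0.0671 with an estimated correlation). In the list of repair Schwann cells, 1 of 12 genes rose, Cxcl5 (adjusted p = 0.000245; adjusted p = 0.0928 with an estimated correlation); in the other lists named here no member was called. Adjusted over the list alone, 6 cholesterol, 9 myelin and 5 adipocyte genes fell and 3 cell cycle and 5 repair Schwann cell genes rose. In the blocked IP, adjusted p was 4.54e-08 for both myelin and cell cycle genes (adjusted p = 0.0882 and 0.0748 with an estimated correlation). The call of Cxcl5 in the IP was lost without injured IP 1 (adjusted p = 0.0732), naive IP 1 (adjusted p = 0.0854) or naive IP 2 (adjusted p = 0.15), and IP calls numbered 5 without injured IP 3 and 4 without naive IP 3. The blocked IP gave 0 calls without injured blocked 2, naive blocked 1 or naive blocked 2, or with only the 6 libraries compared. It gave 8 calls without injured blocked 1, 16 without naive blocked 3 and 21 without injured blocked 3.

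The central question of the design was which transcripts were recovered with PTBP1 above the blocked background, and whether that depended on injury. Rhoa (chromosome 9, 108306129 to 108337934, plus strand, 6 exons), a small GTPase that controls the axonal actin cytoskeleton and is studied as an axonal mRNA, stood at 1430 ± 223 CPM in naive PTBP1 IP and 506 ± 134 CPM in naive blocked IP (SD, n = 3). After injury the levels were 1903 ± 859 and 387 ± 60.3 CPM. All 3 IP libraries lay above all 3 blocked libraries in both states. The log2 fold changes were 1.499 (SE 0.51, adjusted p = 0.231) and 2.30 (SE 0.52, adjusted p = 0.217) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, so neither passed. After injury Rhoa passed in DESeq2 (adjusted p = 0.000377), the likelihood-ratio test (adjusted p = 0.0185) and limma-voom (adjusted p = 0.0398), and the authors' deposited table gives it an FDR of 0.00921. The difference between the 2 states, 0.80 (SE 0.70, adjusted p = 0.926), did not pass.

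None of the other candidates passed in PTBP1 IP over blocked IP by the same edgeR test. Kpnb1 (chromosome 11, 97159714 to 97187881), an importin whose axonal translation signals injury, had log2 fold changes of -0.10 in naive (adjusted p = 0.981) and -0.04 in injured nerve (adjusted p = 0.995). Ncl, the mRNA of nucleolin (chromosome 1, 86344719 to 86359400), was at 0.04 (adjusted p = 0.995) and -0.24 (adjusted p = 0.953). Mtor, the growth kinase (chromosome 4, 148448611 to 148557683), was at 0.71 (adjusted p = 0.906) and -1.03 (adjusted p = 0.867). The main Ptbp1 transcript (chromosome 10, 79854629 to 79864771) was at 1.37 (adjusted p = 0.751) and -0.32 (adjusted p = 0.977) and its retained-intron transcript at 2.38 (adjusted p = 0.612) and 1.29 (adjusted p = 0.881). The signs of the Kpnb1 values, the naive Ncl value and the injured Mtor and Ptbp1 values turned under another scaling or with libraries left out. In input Mtor fell from 34.3 ± 1.37 to 12.5 ± 4.71 CPM (log2 fold change -1.46, SE 0.36, adjusted p = 0.00923) and Ncl rose from 291 ± 67.3 to 612 ± 306 CPM (1.07, SE 0.32, adjusted p = 0.0267; SD, n = 3). The Ncl call was lost without injured input 1 (adjusted p = 0.19), injured input 2 (adjusted p = 0.0509), naive input 2 (adjusted p = 0.0981) or naive input 3 (adjusted p = 0.0794), and with library totals (adjusted p = 0.409). Kpnb1 (0.24, adjusted p = 0.41) and Rhoa (-0.36, adjusted p = 0.218) did not pass in input.

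**Figure D2:**
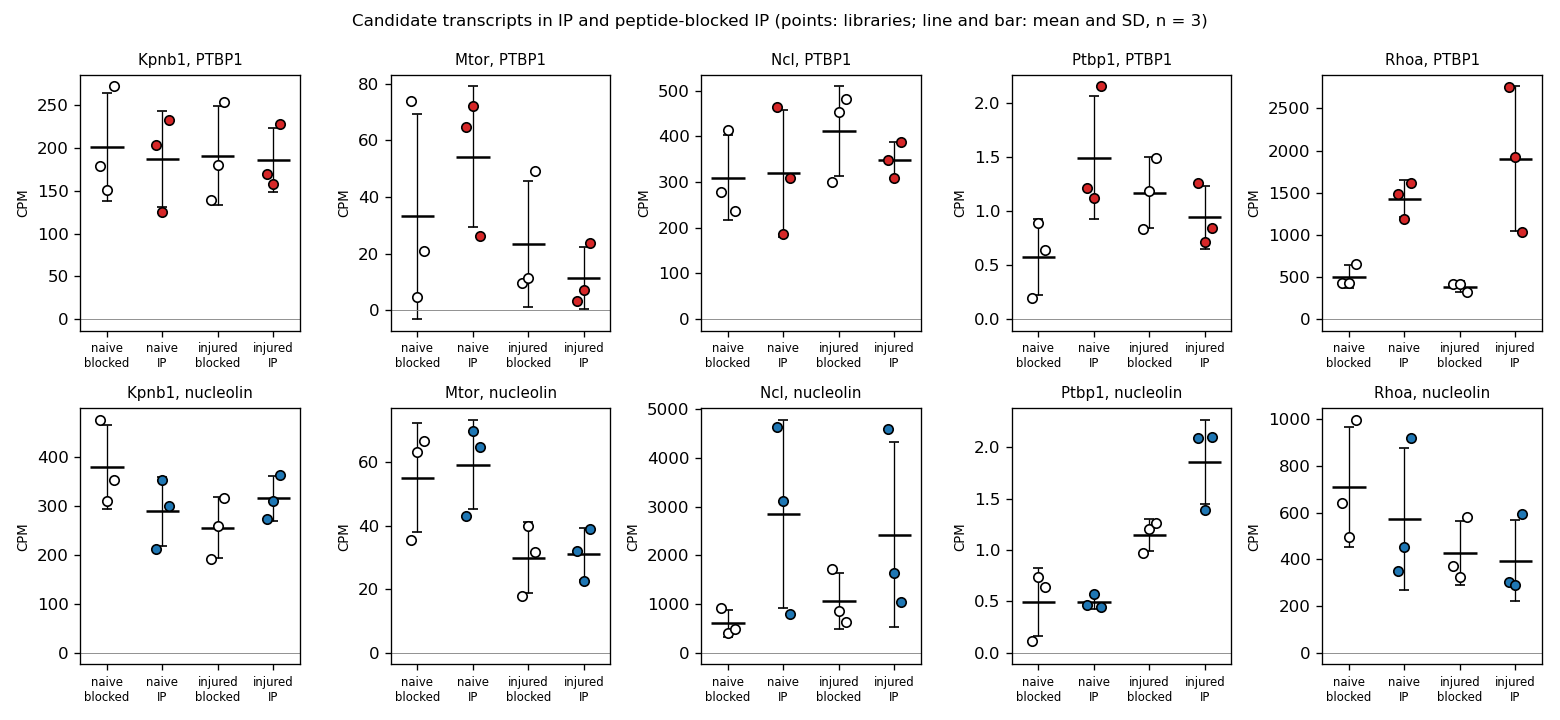
CPM (linear y axis) of Kpnb1, Mtor, Ncl, Ptbp1 and Rhoa in naive blocked IP, naive IP, injured blocked IP and injured IP, with PTBP1 libraries in the top panels and nucleolin libraries in the bottom panels. Open points are blocked libraries, filled points IP libraries, and lines with bars the mean and SD (n = 3); Rhoa in PTBP1 IP lies at 1430 (naive) and 1903 (injured) against 506 and 387 in blocked IP.

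Among all transcripts in PTBP1 IP against blocked IP, those with the smallest p did not pass either. In naive nerve they were Csrnp2, a transcription factor gene (143 ± 103 against 0.436 ± 0.336 CPM, SD, n = 3), Agpat5, a phospholipid-synthesis enzyme (log2 fold change 10.52), the Y-linked demethylase gene Kdm5d (5.08) and several with no blocked count, such as retained-intron transcripts of Ube2e1 (at least 2020-fold higher) and Dph6 (at least 802-fold) and Bard1 (at least 371-fold). All had an adjusted p of 0.222. After injury they were Fcer1g (4.26, 9715 ± 7999 against 506 ± 101 CPM, adjusted p = 0.193), a retained-intron transcript of Rhot1, which tethers mitochondria to motors (at least 378-fold, adjusted p = 0.193), and, among others at an adjusted p of 0.217, the creatine-synthesis gene Gatm (4.01), the actin regulator Marcks (3.29), Ebf1 (3.51), Tram1 (3.36), Rab21 (4.25) and the integrin Itgb1 (2.81).

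By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of 14540 transcripts passed in naive nerve, with 1893 at an unadjusted p under 0.05 (1673 higher, 220 lower). After injury 0 passed, with 1815 at an unadjusted p under 0.05 (1566 higher, 249 lower). Groups lay apart in 13.9% and 22.9% of transcripts, against 10% by chance. Other tools on the same counts called more. In naive nerve DESeq2 called 1014 higher and 85 lower, the likelihood-ratio test 787 and 17 and limma-voom 254 and 6. After injury DESeq2 called 835 and 67, the likelihood-ratio test 775 and 24 and limma-voom 319 and 0. The authors' deposited table of all 12 PTBP1 libraries lists 642 higher and 11 lower in naive and 1148 and 13 in injured nerve at an FDR under 0.05, while their tables of 6 libraries list 699 and 12 in naive and 263 and 11 in injured nerve. The signs in the table of 12 were those found here in 620 of 620 and 1020 of 1021 transcripts. Without injured PTBP1 IP 3, 4 transcripts passed after injury. The biological coefficient of variation was 1.24, and in simulated data from these libraries 22% of 16-fold and 36% of 64-fold changes were recovered in naive nerve, and 22% and 56% after injury. Those changes were set only in transcripts with a mean of at least 5 CPM.

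The change of PTBP1 enrichment with injury also called 0 transcripts by the edgeR test, with 1147 at an unadjusted p under 0.05. The smallest p belonged to retained-intron transcripts of Rhot1, Dph6 and Fndc3a and to Serpinb6a and Prdm1, among others, at an adjusted p of 0.541. DESeq2 called 415 transcripts (169 higher, 246 lower), the likelihood-ratio test 133 and limma-voom 0. Of the simulated 64-fold changes in enrichment, 42% were recovered.

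Nucleolin IP against blocked nucleolin IP asked the same of nucleolin. The transcripts nearest to the threshold included forms with retained introns. A retained-intron transcript of Htt, the huntingtin gene (chromosome 5, 34886451 to 34903724, 8 exons), was at 156 ± 49.0 CPM in naive IP and 4.03 ± 2.95 CPM in naive blocked IP (log2 fold change 5.27, SE 0.75) (SD, n = 3). In naive nerve it was joined, at an adjusted p of 0.0528, by retained-intron transcripts of the splicing regulator Rbm5 (5.14) and of Birc6 (at least 65.4-fold higher), by Creb5 (3.30) and the ceramidase Asah2 (4.88). After injury the peroxisomal catalase Cat (8379 ± 6431 against 307 ± 39.3 CPM), Klf6 (2.73), Egfl6 (5.05), Acot2 (4.55) and Ubap2l (4.58) stood at an adjusted p of 0.102 with the Htt transcript (4.49). Ncl itself was at 2843 ± 1934 in naive IP and 604 ± 279 CPM in naive blocked IP (2.23, SE 0.72, adjusted p = 0.203), and at 1.19 after injury (adjusted p = 0.945). It passed in naive nerve with DESeq2 (adjusted p = 0.0277) and the likelihood-ratio test (adjusted p = 0.0431). The authors' deposited table gives it an FDR of 0.0288. In naive and injured nerve Kpnb1 was at -0.40 (adjusted p = 0.701) and 0.30 (adjusted p = 0.998), Mtor at 0.10 (adjusted p = 0.957) and 0.06 (adjusted p = 0.998), Rhoa at -0.31 (adjusted p = 0.837) and -0.11 (adjusted p = 0.998) and Ptbp1 at -0.01 (adjusted p = 0.995) and 0.70 (adjusted p = 0.997). The signs of both Mtor values, both Rhoa values and the naive Ptbp1 value turned under another scaling or with a library left out.

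By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of 11840 transcripts passed in naive nerve, with 1422 at an unadjusted p under 0.05 (985 higher, 437 lower). After injury 0 passed, with 769 at an unadjusted p under 0.05 (641 higher, 128 lower). Groups lay apart in 18.5% and 18% of transcripts, against 10% by chance. In naive nerve DESeq2 called 693 higher and 68 lower, the likelihood-ratio test 475 and 29 and limma-voom 259 in all. After injury DESeq2 called 309 and 5, the likelihood-ratio test 223 and 2 and limma-voom 14 and 0. The naive count was set by single libraries. Without naive blocked 3 it was 320 (302 higher, 18 lower), without naive IP 3 it was 135 (125 higher, 10 lower), and library totals gave 39. After injury 15 transcripts passed without injured IP 3. In simulated data 68% of 16-fold changes were recovered in naive and 54% in injured nerve. The authors' deposited table lists 732 higher and 38 lower in naive nerve, with the sign found here in 557 of 557. It lists 102 and 4 after injury, but the deposited folds of that comparison correlated with the 3-against-3 folds of the deposited counts at only 0.565, so those calls were not relied on.

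The change of nucleolin enrichment with injury called 0 transcripts, with 302 at an unadjusted p under 0.05 and a smallest adjusted p of 1 by the edgeR test. Cenpk, a kinetochore gene, a retained-intron transcript of P4ha2, a collagen prolyl hydroxylase, Atp6v0d2 (3.25) and a noncoding transcript of Cln3 were among the smallest p. DESeq2 called 20 transcripts, the likelihood-ratio test 6 and limma-voom 0, and 5 passed without naive blocked 3.

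As sets, ribosomal protein and adipocyte genes lay below blocked IP in all 4 IP comparisons. Each gene was represented by a single transcript, which need not be its main form. For ribosomal proteins 67 of 79 members lay below 0 in naive PTBP1 IP (adjusted p = 3.11e-05), 65 of 79 in injured PTBP1 IP (adjusted p = 4.81e-09), 67 of 77 in naive nucleolin IP (adjusted p = 0.00344) and 63 of 77 in injured nucleolin IP (adjusted p = 3.05e-05). For adipocytes the adjusted p was 4.02e-05, 0.00498, 0.00426 and 4.07e-06 in the same order. No member was called, and none of the lists passed with an estimated correlation (adjusted p = 0.966, 0.932, 0.884 and 0.887 for ribosomal proteins and 0.966, 0.932, 0.884 and 0.88 for adipocytes). Adjusted over the list alone, 6 adipocyte genes were lower in injured PTBP1 IP and 0 in the other 3 comparisons, and 0 ribosomal genes in any. Published targets did not pass as sets. The nucleolin targets had an adjusted p of 0.664 in naive and 0.839 in injured nucleolin IP, and the PTBP1 targets 0.752 and 0.81 in PTBP1 IP; adjusted over the list alone, 2 PTBP1 targets were higher after injury. Axonal mRNAs had adjusted p of 0.606 and 0.81 in PTBP1 IP and 0.132 and 0.6 in nucleolin IP.

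Transcripts annotated with a retained intron were higher than blocked IP more often than protein-coding ones, as were other noncoding transcripts and pseudogenes. At an unadjusted p under 0.05, 22.2% of them were higher in naive PTBP1 IP against 7.64% of protein-coding transcripts, and 19.8% against 7.31% after injury. For nucleolin the shares were 18.6% against 5.88% in naive and 10.3% against 4.15% in injured nerve. Other noncoding transcripts and pseudogenes reached 19.4% and 18.8% for PTBP1 and 14.0% and 8.64% for nucleolin in naive and injured nerve. The median log2 fold change of retained-intron transcripts was 1.16, 1.08, 1.06 and 0.75 in that order, and that of the other noncoding class 0.43, 0.46, 0.26 and 0.23. These transcripts were less abundant, with a median of 3.19 CPM against 21.5 CPM for protein-coding transcripts in the PTBP1 libraries and 5.70 against 37.4 CPM in the nucleolin libraries. Intron-containing reads of unspliced RNA and of such transcripts cannot be told apart in these counts.

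**Figure D3:**
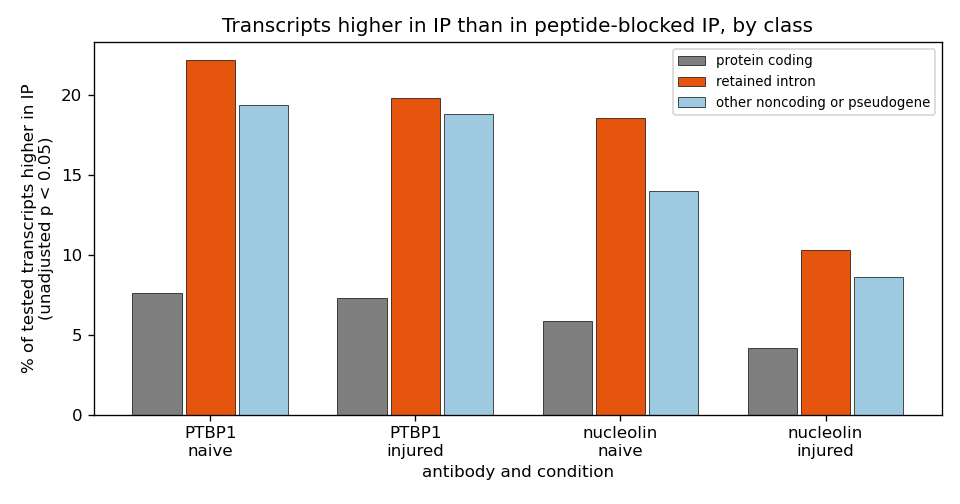
Percent of tested transcripts higher in IP than in blocked IP at an unadjusted p under 0.05 (y axis, from 0), for PTBP1 and nucleolin in naive and injured nerve. Grey bars are protein-coding transcripts, orange bars retained-intron transcripts and light blue bars other noncoding transcripts or pseudogenes; retained-intron bars reach 22.2%, 19.8%, 18.6% and 10.3% against 7.64%, 7.31%, 5.88% and 4.15% for protein-coding bars.

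IP libraries were also set against input, where the transcripts called were nearly all higher in the IP. For PTBP1 26 of 12393 transcripts were higher and 1 lower in naive nerve, and 119 higher and 8 lower after injury. For nucleolin 114 of 10891 were higher and 1 lower in naive nerve, and 40 and 4 after injury, all by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Retained-intron transcripts made up 1015 of the 10891 transcripts tested for nucleolin, with 10 of the 115 calls in naive and 3 of the 44 in injured nerve. For PTBP1 they made up 1435 of the 12393 tested, with 2 of the 27 calls in naive and 1 of the 127 in injured nerve. At an unadjusted p under 0.05, 6.41% of them were higher than input in naive PTBP1 IP, against 5.25% of protein-coding transcripts, and 4.60% against 6.07% after injury; for nucleolin the shares were 14.0% against 8.67% and 8.28% against 8.60%. Median log2 fold changes over input of retained-intron and protein-coding transcripts were 0.13 and -0.06 in naive PTBP1 IP, 0.27 and -0.13 in injured PTBP1 IP, 0.81 and 0.01 in naive nucleolin IP and 0.61 and -0.03 in injured nucleolin IP. Blocked IP against input in the same fits gave 0 calls for both antibodies in naive nerve (unadjusted p under 0.05 for 1821 transcripts with PTBP1 and 1398 with nucleolin) and 0 for injured nucleolin (1389), and 1 higher and 1 lower for injured PTBP1 (1834). At an unadjusted p under 0.05 the IP itself differed from input in 922 transcripts in naive and 1119 in injured PTBP1, fewer than the blocked IP, and in 1488 and 1606 for nucleolin. Of the transcripts called higher than input, 19 of 26 in naive and 82 of 119 in injured PTBP1, and 111 of 114 and 35 of 40 for nucleolin, were also higher than blocked IP at an unadjusted p under 0.05. Both comparisons share the IP libraries, so such agreement is favoured by the selection and is no independent support. The input table lists only transcripts with at least 5 counts in both injured input 2 and injured input 3, so transcripts absent from either were not tested.

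Each of these counts rested on single libraries and on the scaling or fit. With 1 library left out, each was highest without library 3 of the IP, the library of its group with the fewest transcripts at 0. For naive PTBP1, 0 transcripts passed without naive IP 1, naive IP 2 or any naive input and 209 without naive IP 3, DESeq2 size factors left 1, and limma-voom called 0. For injured PTBP1, 0 passed without injured IP 1 or any injured input, 3 without injured IP 2 and 372 without injured IP 3, and limma-voom called 0. For naive nucleolin, 0 passed without any naive input, 5 without naive IP 1, 33 without naive IP 2 and 581 without naive IP 3, and limma-voom called 12. For injured nucleolin, 0 passed without injured IP 1 or any injured input, 4 without injured IP 2 and 431 without injured IP 3; limma-voom called 1 and library totals 253.

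The last comparison asked whether the antibodies recovered the same genes. With 0 genes past the threshold in any IP against blocked IP by edgeR's quasi-likelihood test, 0 genes were shared between PTBP1 and nucleolin or between naive and injured nerve. Among genes higher at an unadjusted p under 0.05, chosen after the data were seen, PTBP1 and nucleolin shared 186 in naive nerve and 127 after injury. The sizes of the lists give 85.8 and 53.8 by chance. Naive and injured nerve shared 627 genes for PTBP1 (194 by chance) and 413 for nucleolin (58.2 by chance). Under the likelihood-ratio test the corresponding shared counts were 50, 28, 219 and 156, against 20.2, 8.89, 47.5 and 10.1 by chance. These counts were above the values from list sizes but do not by themselves show shared targets. Naive and injured tests of an antibody came from the same fit with a shared estimate of spread, which favours passing in both. Genes with several tested transcripts also had more ways to be shared. The chance values take account of neither. The lists drew unevenly on input levels, and whether that accounts for the excess was not tested. In naive nerve 669 transcripts in the lowest and 164 in the highest of 3 input classes were higher for PTBP1, and 392 and 211 for nucleolin. After injury the numbers were 590 and 243 for PTBP1, and 182 and 196 for nucleolin, which went the other way.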

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

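The tests of whether injury changes in nucleolin IP follow input or blocked IP were chosen after the result was seen, as were the shares at 0 counts by input class.

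Named transcripts of both antibodies were screened for IP and blocked libraries that lay fully apart in opposite directions in naive and injured nerve. Only Sgol2a in nucleolin IP against blocked IP was picked out. Every naive IP library lay above every naive blocked library, and every injured IP library below every injured blocked library. The log2 ratio of the mean CPM of Sgol2a in naive nerve was 3.99, with 0.1 CPM added to each mean and no model fitted. Naive IP libraries held 13.5, 2.75 and 6.73 CPM and naive blocked libraries 0.93, 0 and 0.231 CPM; injured IP libraries held 19.2, 20.4 and 28.2 CPM and injured blocked libraries 34.1, 58.1 and 34.5 CPM. The difference between the states was -5.18 on the log2 scale (SE 1.594, adjusted p = 1 by edgeR's quasi-likelihood test), so it did not pass.

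More transcripts were higher than lower in IP against blocked IP. Transcripts were listed only with at least 5 counts in all 3 libraries of 1 group. Whether this filter admitted more of them through the IP than through the blocked IP was not tested. Loss of transcripts from blocked libraries of low complexity was tested among transcripts of the highest of 3 input CPM classes, where 0.129% to 1.41% were at 0 counts in blocked libraries (means of 3 libraries), against 11.4% to 36.3% in the lowest class. There the ratio of higher to lower was 0.955 in naive nucleolin IP (0.481 to 2.05 with 1 library left out, against 5.16 in the lowest class), which that loss predicts, although the range passes the bound of 1.5 set for it. It was 2.1 in naive PTBP1 IP (1.31 to 6.6), 2.27 in injured PTBP1 IP (1.24 to 7.7) and 2.51 in injured nucleolin IP (1.12 to 12.4), where loss and binding cannot be told apart because single libraries move the ratio across both bounds. The ratio of 0.955 does not by itself speak for loss, because it depends on where the scaling sets 0. That class had a median log2 fold change of -0.28, and other scalings were not run by class. Binding to the antibody's protein stays open as untested in all 4.

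Retained-intron transcripts lay higher in nucleolin IP over blocked IP than protein-coding ones. After matching on input CPM the difference in median log2 fold change was 1.18 in naive (1.01 to 1.82 with 1 library left out) and 0.743 in injured nerve (0.584 to 1.04), which argues against low input abundance alone as the whole cause. That match held the 1015 of 1256 retained-intron transcripts also listed in input. After matching on length the difference was 1.4 (1.14 to 1.99) and 0.955 (0.78 to 1.41), which argues in the same way against short length alone. Both matches were run separately, so abundance and length acting together were not tested. PTBP1 IP showed a like difference after matching on input CPM (1.16 in naive and 0.869 in injured nerve), so it is not particular to nucleolin. A list of 10 nuclear RNAs, the only measure of nuclear carry-over here, had median log2 fold changes of -0.328 in naive and 0.00561 in injured nerve (adjusted p = 0.98 and 0.6), with members on both sides of 0, which decides nothing. Carry-over of unspliced RNA, binding by nucleolin, and abundance and length acting together stay open.

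Transcripts called in nucleolin IP, injured against naive, had the sign of the input comparison in 100% and that of the blocked IP comparison in 99% of cases, against 78.4% and 72.8% over all transcripts. Both a change in RNA abundance and a change in RNA carried over without binding predict this, and it could have come out otherwise. The change of enrichment itself called 0 transcripts. A change in binding on top of these stays open, since 44% of simulated 16-fold changes in enrichment were recovered.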

How the results depend on the processing

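The likelihood-ratio test, limma-voom, counts summed per gene, replicates 1 and 2 alone, the removal of Yam1, Lars2 and Gm15564, overlaps at an unadjusted p and list tests with a block were chosen after seeing the data. Apart from single libraries left out, named genes kept direction and side of the threshold in 3717 cases, passed newly in 232, no longer passed in 182 and turned in 43. With 1 library left out the numbers were 2002, 40, 328 and 48. Values given for genes are log2 fold changes. Where a value below differs from the report the cause was not tested, except that fewer libraries were used where some were left out. The main numbers of calls were 0 for naive PTBP1 IP over blocked IP, 0 for injured PTBP1 IP over blocked IP, 0 for the change of PTBP1 enrichment, 1 for PTBP1 IP after injury, 4 for PTBP1 blocked IP after injury, 27 for naive PTBP1 IP over input, 127 for injured PTBP1 IP over input, 0 for naive nucleolin IP over blocked IP, 0 for injured nucleolin IP over blocked IP, 0 for the change of nucleolin enrichment, 98 for nucleolin IP after injury, 184 for nucleolin blocked IP after injury, 115 for naive nucleolin IP over input, 44 for injured nucleolin IP over input and 3924 for input after injury. The filters on low counts moved no number of calls by over 1.5 times. The limit of 1 on the absolute log2 fold change was run only for IP against blocked IP and the overlaps, where 0 calls could not fall. Depth limits what could be seen: the tables list only transcripts past a count limit, and injured input 1 held 7536033 counts. Simulated 4-fold changes were recovered in 0 to 12% of cases in the IP and blocked IP comparisons and in 82% in input, which holds that library; the coefficient of variation was 1.24 for PTBP1, 0.84 for nucleolin and 0.417 for input.

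The Wald test of DESeq2 called 1099 for naive PTBP1 IP over blocked IP, 902 for injured PTBP1 IP over blocked IP, 415 for the change of PTBP1 enrichment, 676 for PTBP1 IP after injury, 2497 for PTBP1 blocked IP after injury, 399 for naive PTBP1 IP over input and 669 for injured PTBP1 IP over input. Among nucleolin comparisons it called 761 for naive nucleolin IP over blocked IP, 314 for injured nucleolin IP over blocked IP, 20 for the change of nucleolin enrichment, 725 for nucleolin IP after injury, 1623 for nucleolin blocked IP after injury, 596 for naive nucleolin IP over input and 717 for injured nucleolin IP over input. Signs turned for Kpnb1 0.10 in injured PTBP1 IP over blocked IP, 0.15 in PTBP1 IP after injury and 0.000431 in PTBP1 blocked IP after injury, the retained-intron transcript of Ptbp1 0.0483 in PTBP1 blocked IP after injury, Ptbp1 0.12 in naive nucleolin IP over blocked IP. DESeq2 size factors in edgeR called 1 for naive PTBP1 IP over input and 197 for injured PTBP1 IP over input. Signs turned for Kpnb1 0.10 in injured PTBP1 IP over blocked IP, 0.15 in PTBP1 IP after injury and 0.000401 in PTBP1 blocked IP after injury, the retained-intron transcript of Ptbp1 0.0321 in PTBP1 blocked IP after injury, Ptbp1 0.12 in naive nucleolin IP over blocked IP. Scaling to library totals called 81 for injured PTBP1 IP over input and 2327 for input after injury. With nucleolin libraries it called 39 for naive nucleolin IP over blocked IP and 253 for injured nucleolin IP over input. Signs turned for Ncl -0.29 in naive PTBP1 IP over blocked IP, Kpnb1 -0.23 in the change of PTBP1 enrichment, 0.19 in PTBP1 blocked IP after injury and -0.0204 in input after injury, the retained-intron transcript of Ptbp1 0.0813 in PTBP1 blocked IP after injury, Mtor -0.0927 in injured nucleolin IP over blocked IP. A fit of only the groups compared called 12 for PTBP1 IP after injury, 0 for PTBP1 blocked IP after injury, 0 for naive PTBP1 IP over input and 877 for injured PTBP1 IP over input. Among nucleolin comparisons it called 495 for nucleolin IP after injury, 0 for nucleolin blocked IP after injury, 316 for naive nucleolin IP over input and 1129 for injured nucleolin IP over input. Signs turned for Kpnb1 0.0358 in injured PTBP1 IP over blocked IP and 0.12 in PTBP1 IP after injury.

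The likelihood-ratio test called 804 for naive PTBP1 IP over blocked IP, 799 for injured PTBP1 IP over blocked IP, 133 for the change of PTBP1 enrichment, 318 for PTBP1 IP after injury, 1821 for PTBP1 blocked IP after injury, 225 for naive PTBP1 IP over input and 369 for injured PTBP1 IP over input. With nucleolin libraries it called 504 for naive nucleolin IP over blocked IP, 225 for injured nucleolin IP over blocked IP, 6 for the change of nucleolin enrichment, 400 for nucleolin IP after injury, 1008 for nucleolin blocked IP after injury, 321 for naive nucleolin IP over input and 380 for injured nucleolin IP over input. The limma-voom test called 260 for naive PTBP1 IP over blocked IP, 319 for injured PTBP1 IP over blocked IP, 214 for PTBP1 IP after injury, 637 for PTBP1 blocked IP after injury, 0 for naive PTBP1 IP over input and 0 for injured PTBP1 IP over input. Among nucleolin comparisons it called 259 for naive nucleolin IP over blocked IP, 14 for injured nucleolin IP over blocked IP, 678 for nucleolin blocked IP after injury, 12 for naive nucleolin IP over input and 1 for injured nucleolin IP over input. Signs turned for Kpnb1 0.035 in PTBP1 IP after injury, the retained-intron transcript of Ptbp1 0.51 in PTBP1 blocked IP after injury, Mtor 0.0378 in PTBP1 blocked IP after injury and 0.0195 in the change of nucleolin enrichment, Ptbp1 0.35 in naive nucleolin IP over blocked IP. Summing counts per gene called 4 for PTBP1 IP after injury. With nucleolin libraries it called 24 for naive nucleolin IP over blocked IP and 106 for injured nucleolin IP over input. Signs turned for the retained-intron transcript of Ptbp1 -0.00654 in injured PTBP1 IP over blocked IP and 0.94 in PTBP1 blocked IP after injury, Kpnb1 0.0319 in PTBP1 IP after injury, Ptbp1 0.0116 in naive nucleolin IP over blocked IP, Cln3 0.44 in the change of nucleolin enrichment. Using replicates 1 and 2 alone called 56 for naive PTBP1 IP over blocked IP, 6 for injured PTBP1 IP over blocked IP, 7 for PTBP1 IP after injury, 16 for PTBP1 blocked IP after injury, 174 for naive PTBP1 IP over input and 299 for injured PTBP1 IP over input. Among nucleolin comparisons it called 116 for naive nucleolin IP over blocked IP, 50 for injured nucleolin IP over blocked IP, 0 for nucleolin IP after injury, 94 for nucleolin blocked IP after injury, 410 for naive nucleolin IP over input and 476 for injured nucleolin IP over input. Signs turned for Ncl -0.0447 in naive PTBP1 IP over blocked IP, Kpnb1 0.0186 in naive PTBP1 IP over blocked IP, 0.15 in injured PTBP1 IP over blocked IP, 0.25 in PTBP1 IP after injury and 0.12 in PTBP1 blocked IP after injury, Ptbp1 0.085 in injured PTBP1 IP over blocked IP, 0.00802 in PTBP1 IP after injury and 0.33 in naive nucleolin IP over blocked IP, Rhoa 0.15 in PTBP1 blocked IP after injury, the retained-intron transcript of Ptbp1 2.14 in PTBP1 blocked IP after injury, Mtor -0.0262 in injured nucleolin IP over blocked IP. Removal of Yam1, Lars2 and Gm15564 called 43 for naive PTBP1 IP over input.

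With the replicate number as a block the fit called 6 for PTBP1 IP after injury, 43 for PTBP1 blocked IP after injury and 42 for naive PTBP1 IP over input. With nucleolin libraries it called 334 for nucleolin IP after injury, 475 for nucleolin blocked IP after injury, 295 for naive nucleolin IP over input and 393 for injured nucleolin IP over input. Signs turned for Kpnb1 0.00113 in PTBP1 IP after injury, Ptbp1 0.10 in naive nucleolin IP over blocked IP, Mtor 0.0248 in the change of nucleolin enrichment. Under the block by lysate pool the sign turned for Ptbp1 0.25 in naive nucleolin IP over blocked IP. In the other pair of groups with every same-number correlation over 0.1, injured PTBP1 IP and its blocked IP, the block changed no call. Over all group pairs, same-number correlations ran from -0.0425 to 0.532, and in 32 of 39 same-number pairs the library correlated best with its own number, a hint from the data and not from the design. Library 3 did so in every pair of groups, and the pairs that failed were all of numbers 1 and 2.

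With an estimated correlation the number of lists past the threshold went from 2 to 0 for naive PTBP1 IP over blocked IP, 2 to 0 for injured PTBP1 IP over blocked IP, 12 to 0 for PTBP1 IP after injury, 12 to 0 for PTBP1 blocked IP after injury, 2 to 0 for naive nucleolin IP over blocked IP, 2 to 0 for injured nucleolin IP over blocked IP, 8 to 1 for nucleolin IP after injury, 8 to 0 for nucleolin blocked IP after injury and 10 to 5 for input after injury. With the replicate block and an estimated correlation it was 0 for injured PTBP1 IP over blocked IP and 3 for nucleolin IP after injury. Genes shared at an unadjusted p under 0.05, against 0 in the main test, were 186 between PTBP1 and nucleolin for naive, 127 between PTBP1 and nucleolin for injured, 627 between naive and injured for PTBP1 and 413 between naive and injured for nucleolin. The sizes of the lists alone give 85.8, 53.8, 194 and 58.2, in that order. Genes shared under the likelihood-ratio test, against 0 in the main test, were 50 between PTBP1 and nucleolin for naive, 28 between PTBP1 and nucleolin for injured, 219 between naive and injured for PTBP1 and 156 between naive and injured for nucleolin. The sizes of those lists alone give 20.2, 8.89, 47.5 and 10.1.

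With 1 library left out, calls ran from 0 to 0 for naive PTBP1 IP over blocked IP, 0 to 4 for injured PTBP1 IP over blocked IP, 0 to 0 for the change of PTBP1 enrichment, 0 to 5 for PTBP1 IP after injury, 0 to 21 for PTBP1 blocked IP after injury, 0 to 209 for naive PTBP1 IP over input and 0 to 372 for injured PTBP1 IP over input. For nucleolin they ran from 0 to 320 for naive nucleolin IP over blocked IP, 0 to 15 for injured nucleolin IP over blocked IP, 0 to 5 for the change of nucleolin enrichment, 2 to 27 for nucleolin IP after injury, 13 to 419 for nucleolin blocked IP after injury, 0 to 581 for naive nucleolin IP over input and 0 to 431 for injured nucleolin IP over input, and for input from 2514 to 3821. Ncl ran from -0.28 to 0.31 in naive PTBP1 IP over blocked IP, -0.56 to 0.12 in the change of PTBP1 enrichment, -0.15 to 0.54 in PTBP1 IP after injury and -1.08 to 0.32 in nucleolin IP after injury. Kpnb1 ran from -0.29 to 0.18 in naive PTBP1 IP over blocked IP, -0.23 to 0.31 in injured PTBP1 IP over blocked IP, -0.23 to 0.36 in the change of PTBP1 enrichment, -0.24 to 0.17 in PTBP1 IP after injury, -0.24 to 0.21 in PTBP1 blocked IP after injury and -0.0489 to 0.30 in nucleolin IP after injury. Mtor ran from -2.15 to 0.20 in injured PTBP1 IP over blocked IP, -1.55 to 0.97 in PTBP1 blocked IP after injury, -0.0784 to 0.29 in naive nucleolin IP over blocked IP, -0.16 to 0.31 in injured nucleolin IP over blocked IP and -0.32 to 0.21 in the change of nucleolin enrichment. The retained-intron transcript of Ptbp1 ran from -0.41 to 1.95 in injured PTBP1 IP over blocked IP and -0.79 to 2.13 in PTBP1 blocked IP after injury. Ptbp1 ran from -0.41 to 0.43 in naive nucleolin IP over blocked IP. Rhoa ran from -0.83 to 0.0127 in naive nucleolin IP over blocked IP, -0.48 to 0.27 in injured nucleolin IP over blocked IP and -0.23 to 0.72 in the change of nucleolin enrichment.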

Other observations

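The values under the likelihood-ratio test and the matched values for PTBP1 below were chosen after the result was seen.

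In PTBP1 IP over blocked IP, retained-intron transcripts exceeded protein-coding ones by 1.16 in median log2 fold change after matching on input CPM in naive nerve (0.591 to 2.2 with 1 library left out) and 0.869 after injury (0.77 to 1.37). After matching on length the values were 1.42 (0.921 to 2.81) and 1.35 (1.03 to 1.87). Among the authors' calls for higher in IP at an FDR under 0.05, 26.1% were retained-intron transcripts in injured and 25.4% in naive PTBP1, against 13.2% of those tested, and 26% in naive nucleolin, against 10.6%.

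Other splits of the same libraries were tested in each comparison; with 10 splits the share as large cannot be under 0.05. For IP against blocked IP, 10 of 10 splits gave as many calls as the real groups for naive PTBP1 (real 0, highest other 2), injured PTBP1 (0 and 0), naive nucleolin (0 and 0) and injured nucleolin (0 and 0). With 0 real calls every split reaches that number, so these results were fixed in advance and decide nothing. For the change of enrichment, 100 of 100 splits gave as many calls for PTBP1 (0 and 1) and nucleolin (0 and 99), again fixed by the 0 real calls. These splits exchanged naive and injured libraries within the IP and within the blocked IP. An injury change shared by IP and blocked IP can then enter the contrast, so the 99 calls do not test chance. For injury, 1 of 10 splits gave as many calls as the real groups in PTBP1 IP (1 and 0), PTBP1 blocked IP (4 and 0), nucleolin IP (98 and 0) and input (3924 and 0). In nucleolin blocked IP 2 of 10 did so (184 and 216), where the split with 216 calls set naive blocked 3 with injured blocked 2 and 3, and so kept 2 of 3 libraries of each state together. For IP against input 1 of 10 did so in naive PTBP1 (27 and 0), injured PTBP1 (127 and 0), naive nucleolin (115 and 0) and injured nucleolin (44 and 0). Under the likelihood-ratio test the real groups and the highest other split called 804 and 412 transcripts in naive PTBP1, 799 and 10 in injured PTBP1, 504 and 40 in naive nucleolin and 225 and 17 in injured nucleolin.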
